A study of Mus musculus with 3 samples.

How the data were processed

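Single-cell RNA of Pten-null mouse prostate tumours was measured in 3 libraries, 1 non-castrated and 2 castrated, each from 3 sorted fractions mixed in equal numbers. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat (version not given) were used with genome build mm10. Per the labels, libraries were made with the 3′ v3 kit. The deposited values were taken as natural log values, and none was below 0. They reached 8.12 and were above 0 in 73.3% of all gene and cell pairs, far more than counts of single cells give, so they are smoothed or imputed values. The smoothing method, the log base and the scale are not given in the sources used here. Natural log of counts per 10000 plus 1 was assumed, and values were back-transformed on that scale only where stated.

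The smoothing limits each comparison. The same 1247 genes were at 0 in every cell of both castrated libraries, against 863 in the non-castrated library, with 337 shared. Of 607 genes above 0 in fewer than 300 castrated cells, 0 were missing from either castrated library. The castrated libraries were thus taken as smoothed together and the non-castrated library alone. Smoothing together can pull the castrated libraries towards each other, so the spread between them may be understated, and group differences cannot be separated from separate smoothing. In a simulation of 2 libraries in which 40.8% of each cell's neighbours came from the other library, the share measured here for castrated library 1, averaging over neighbours left 21.0% of the SD between libraries. That outcome follows from the mixing share that was set. The share itself was measured on values that were already smoothed, so it may not be the share that the smoothing used. When each simulated cell was averaged with its nearest cells over both libraries, 103.6% was left, and 103.5% when libraries were smoothed apart. Of the neighbours of non-castrated cells 99.7% were non-castrated. Back-transformed sums per cell had medians of 7082, 5601 and 5632 in the non-castrated library and castrated libraries 1 and 2, and ribosomal protein genes took a median of 21.6%, 4.84% and 6.49% of them. These medians over all cells also carry the cell makeup of each library. In neutrophils the sums had medians of 5430, 5552 and 5603 and in T cells of 7432, 7637 and 7692. They were 7852, 6917 and 7054 in fibroblasts and 7400, 4848 and 4735 in macrophages. The ribosomal protein gene Rpl13 was at 1.85, 1.20 and 1.34 in neutrophils and at 4.18, 4.11 and 4.14 in T cells.

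Columns were assigned by the start of their names. The start of the non-castrated columns names that group and 24 weeks. The other starts carry only the numbers 1 and 2, and were taken as castrated libraries 1 and 2 by elimination and number. The table had 0 columns of other samples.

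Cells with over 20% of their back-transformed sum in mitochondrial genes were left out (5.29%, 4.88% and 5.22% of the libraries). No count filter or doublet caller was applied, since both need counts. The 2000 most variable genes, 30 principal components without integration, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, python-igraph 0.11.9, scikit-learn 1.9.0, seed 1) gave 59 clusters, of which 36 were over 90% non-castrated and 21 over 90% castrated. Clusters were named from markers of 20 cell types fixed before the data were examined, 179 of 187 of which were in the table. A name needed at least 3 markers raised by 0.5 ln units over the other cells of the same libraries, and no other type with more markers among the 10 leading genes. The reference that weighs the 3 compartments equally, the rule that leaves clusters led by Upk3b without a name, and the assignment of red cells to no compartment were set after clusters had been seen. Neutrophils came from clusters 15, 19, 25, 50 and 53 in the non-castrated library and 0, 1, 2, 3, 5, 9 and 20 in the castrated ones, T cells from 7, 10, 22, 33, 37, 45 and 48 against 31 and 36, luminal cells from 14, 16, 24, 30 and 54 against 11, 13, 28 and 56, and fibroblasts from 4, 6, 8, 21, 49 and 51 against 27, with 39 shared. Macrophages came from 18, 32 and 47 against 44, with 58 shared. Shares have exact Clopper-Pearson intervals (scipy 1.17.1) at 95%.

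The design fixed before the data were examined assumed counts and a count model. Since the values are not counts, its fallback was used: class means per library and their differences, without a test. Classes with at least 50 cells in each library were compared (neutrophils, T cells, luminal epithelial cells and fibroblasts), and macrophages are given as values. Means over cells and differences were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and figures drawn with matplotlib 3.10.9. A gene was counted when its mean in the higher group was at least 0.405 ln units (50 CPM on the assumed scale), the difference at least 0.5, and both castrated libraries lay on the same side. The size of 0.5 was chosen once the unit was known.

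Named genes followed a rule fixed in advance except for its p-value: the 8 highest and 8 lowest differences per class over the expression floor, both castrated libraries on 1 side, at 10% or more of the level in the class where the gene is highest, without predicted, ribosomal protein or mitochondrial genes. Added were genes always given and up to 4 members of each list outside the central 95% of random lists. The rule had foreseen 3 per direction if no gene passed a test. The larger number, and the ranking of list members by size of difference, were chosen when the unit was known and before differences were computed. Tacstd2 and Krt4 are among the genes always given.

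Of 35 gene lists fixed before the data were examined (512 of 514 genes in the table), those with at least 5 members at 0.05 ln units or more were placed among 10000 random lists matched on mean expression in 20 bins. On simulated cells drawn from the non-castrated luminal class, 100 of 100 genes changed by 0.6 and 100 of 100 changed by 0.8 were recovered with 0 of 17079 unchanged genes called, over 17279 genes; this simulation holds no variation between animals. Of 400 simulated lists without change, drawn from 7221 genes, 5.25% lay outside the central 95%.

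Alternatives tried were other clustering resolutions (0.5 and 2), mitochondrial limits, ways of naming cells, pseudocounts, filters, rescaling and leaving out each castrated library.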

Results

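The study profiled prostate tumours of mice that lack the tumour suppressor Pten in the prostate epithelium, a model in which tumours form in the presence of androgen and grow on after castration. Single-cell RNA was measured with the 10x Genomics 3′ kit in 3 libraries, 1 from a non-castrated mouse and 2 from castrated tumours. Castration was done at 8 weeks of age and castrated tumours were taken 16 weeks later, at 24 weeks. The labels disagree on the non-castrated mouse, which is given as 10 or as 24 weeks old and as sham-operated or as untreated. Nothing in the labels says that the castrated libraries came from separate animals, so their spread may be technical. Living cells had been sorted into 3 fractions, epithelial (Epcam-positive), immune (Epcam-negative, CD45-positive) and the remaining double-negative cells, which were pooled in equal numbers. Cell shares are therefore given only within each compartment.

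The table held 4162 cells of the non-castrated library, 1682 of castrated library 1 and 1895 of castrated library 2. The values were smoothed expression, taken as natural log values (ln units) because the log base was not given, without counts, so the sequencing depth behind them is unknown. From genes at 0 in every cell, the castrated libraries were taken as smoothed together and the non-castrated library alone. After 401 cells with over 20% mitochondrial RNA were left out, 3942, 1600 and 1796 cells remained. With 1 library against 2, an exact permutation test could not give a p below 0.33, and no test was made. Differences are castrated mean minus non-castrated value in ln units, and a gene was counted as differing when this reached 0.5 with both castrated libraries on the same side. Cell type names below stand for cells that resemble the type by their markers.

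The first comparison asked how the cell makeup of Pten-null tumours differs after castration. Neutrophil-like cells made up most immune cells in both castrated libraries and a smaller part in the non-castrated library. Their share of immune cells was 24.2% in the non-castrated library (471 of 1944 cells, exact 95% interval 22.3 to 26.2%), 80.6% in castrated library 1 (1010 of 1253, 78.3 to 82.8%) and 88.2% in castrated library 2 (1074 of 1218, 86.2 to 89.9%). The difference of 60.2 percentage points compares with an SD of 5.35 between the castrated libraries. T cells had the opposite order, with 41.8%, 6.70% and 7.31% of immune cells. Macrophages made up 13.8%, 2.15% and 2.71%, a difference of -11.4 percentage points that was -4.5 when clusters with none of their own markers among the leading genes were left out, and B cells 9.77%, 4.15% and 1.40%. Natural killer or innate lymphoid cells (6.07%) and conventional dendritic cells (4.32%) formed clusters of their own in the non-castrated library. No cluster given either name held castrated cells, which rests on the clustering and naming and gives no upper limit. The dendritic name was weak: 84 cells had 3 of 10 markers raised and 0 among the leading genes. At resolution 2 only 13 cells were given it. The T cell class of the castrated libraries held natural killer transcripts, with Ncr1 at 0.10 ln units in the non-castrated library and 0.13 and 0.22 in castrated libraries 1 and 2. Intervals cover counting error only.

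Among epithelial cells, luminal cells formed the main class in each library, at 73.3%, 65.8% and 72.2% in the non-castrated library and castrated libraries 1 and 2. Basal cells, which carry keratins 5 and 14, were more frequent in the castrated libraries. They made up 4.83% of epithelial cells in the non-castrated library (36 of 745, 3.41 to 6.63%), 22.5% in castrated library 1 (50 of 222, 17.2 to 28.6%) and 18.7% in castrated library 2 (88 of 471, 15.3 to 22.5%). The castrated basal cluster of 138 cells had all 8 basal markers raised, but 3 basal markers and 3 of another type among its leading genes. The luminal keratin gene Krt8 was at 2.20, 2.42 and 2.61 in basal cells, against 1.96, 2.71 and 2.47 in luminal cells. Seminal vesicle epithelial cells, from the gland that adjoins the prostate, made up 14.0% of non-castrated epithelial cells, and no castrated cell was given this name. Clusters without a name held 7.92%, 11.7% and 9.13% of epithelial cells. The castrated ones formed a single cluster of 26 and 43 cells that resembled seminal vesicle most, with 3 of its 7 markers raised and Pate4 at 4.16 ln units, but had more luminal markers among its leading genes. The missing castrated seminal vesicle class therefore rests on the naming rule, and no upper limit is given.

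Stromal cells were few in the castrated libraries, with 1235, 125 and 107 cells. Fibroblasts made up 85.9%, 46.4% and 52.3% of them, blood endothelial cells 7.53%, 20% and 15.9%, and lymphatic endothelial cells 4.45% in the non-castrated library, with no castrated cell given this name. The lymphatic gene Ccl21a was at 1.26 and 1.16 ln units in the blood endothelial class of the castrated libraries, against 0.10 in the non-castrated one, so no upper limit is given. Clusters led by genes that include the mesothelial gene Upk3b, which were left without a name, held 2.11%, 33.6% and 31.8%. The difference in fibroblast share turned from -36.5 to 5.1 percentage points when no mitochondrial limit was set, since a castrated cluster of this kind was then named fibroblast. No direction is therefore drawn from the fibroblast share.

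**Figure D1:**
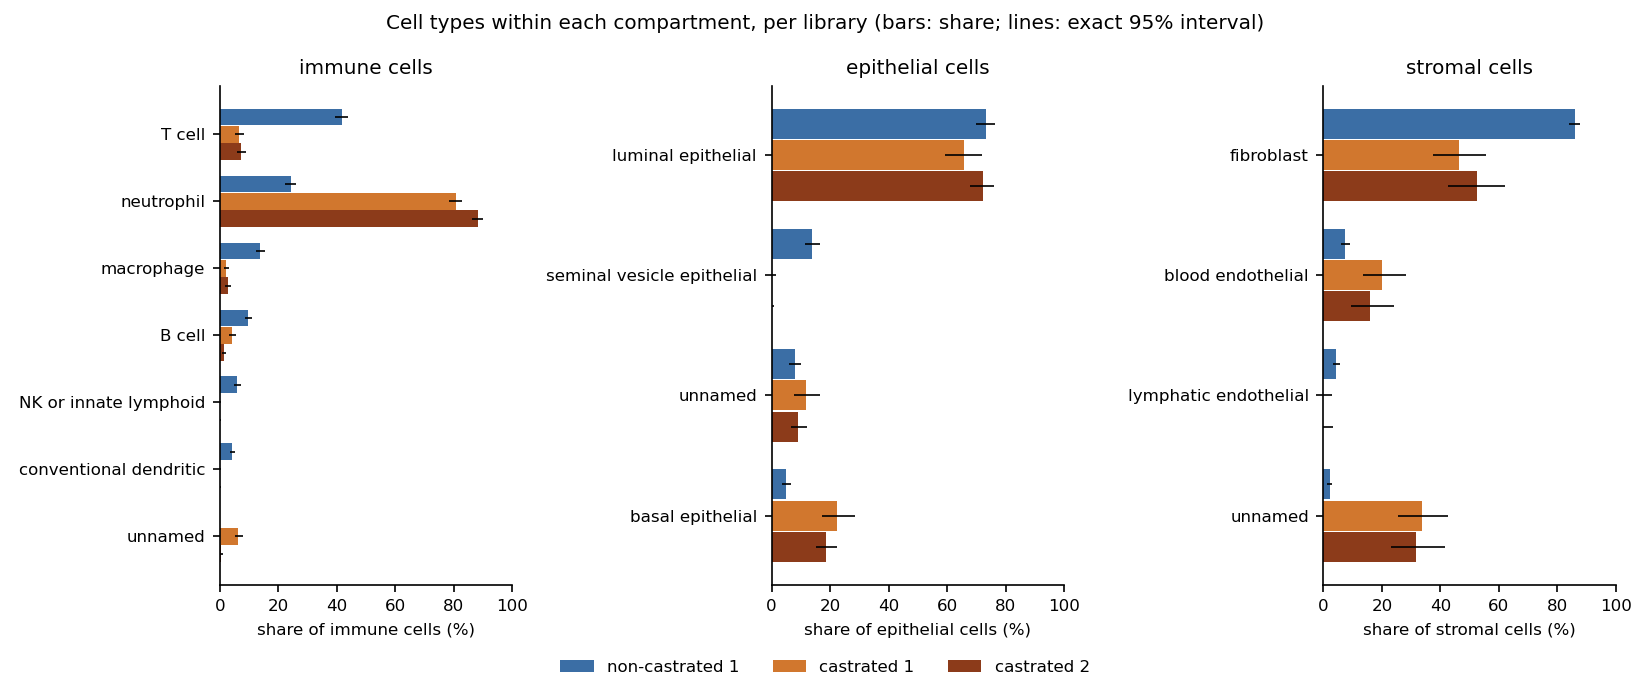
Share of each cell type (x axis, % of the compartment's cells) in immune, epithelial and stromal cells of the non-castrated library (blue) and castrated libraries 1 (orange) and 2 (brown). Bars show the share and lines its exact 95% interval. Neutrophils take 80.6% and 88.2% of castrated immune cells against 24.2% of non-castrated ones.

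The next comparison asked how luminal epithelial cells differ after castration. It rests on 546, 146 and 340 cells. Secreted prostate protein genes were lower in the castrated libraries. Spink1, a trypsin inhibitor secreted by the prostate, had a mean of 2.32 ln units in the non-castrated library and of 0.02 and 0.03 in castrated libraries 1 and 2. It was at 2.45 in the non-castrated seminal vesicle cluster and at 0.87 to 1.89 in the remaining non-castrated classes. Free RNA may therefore make up part of its luminal level. Sbp and Sbpl, spermine-binding proteins of prostatic secretion, differed by -1.90 and -0.79, and Spink5, a protease inhibitor, by -0.72. Of the 9 measured secreted prostate proteins 4 were lower by at least 0.5 and the list's median difference was -0.45. The androgen response list, with 17 measured genes, had 2 that were lower by at least 0.5 (Spink1 and Sbp) and a median of only -0.01, while Fkbp5 and Azgp1 differed by -0.22 and -0.24. Ar, the androgen receptor, was at 0.42, 0.82 and 0.78. Pbsn, the probasin gene whose promoter often drives Cre in this tissue, was at 0.06 in the non-castrated library and close to 0 in the castrated libraries, and Nkx3-1 was close to 0 in all 3.

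Pten itself was at 0.27 in luminal cells of the non-castrated library and at 0.34 and 0.32 in the castrated ones. In fibroblasts it was at 0.57, 0.51 and 0.48. The labels do not say which part of the gene is deleted, so these 3′ values do not check the deletion.

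Luminal genes that were higher in the castrated libraries included Sat1, a polyamine acetyltransferase (1.5 in the non-castrated library, 2.69 and 2.59 in the castrated ones), the carbonic anhydrase gene Car2 (0.64, 1.63 and 1.84), the surface protein gene Ly6d (1.00, 2.01 and 2.01), Cldn4, which encodes a tight junction protein (0.81, 1.91 and 1.51), and Reg3g, an antimicrobial lectin gene (0.46, 1.41 and 1.47). Errfi1, a feedback inhibitor of the EGF receptor, differed by 0.89, Lars2, a mitochondrial leucyl-tRNA synthetase, by 0.98 and Jun by 1.02. Jun, Cldn4 and Lars2 were among the leading genes of a luminal cluster of 2, 40 and 51 cells and of another of 28 non-castrated cells. Without a mitochondrial limit, clusters led by these genes held 69 and 94 castrated and 60 non-castrated cells. Their class differences therefore depend on the mix of such cells in each library. The list of genes of castration-tolerant luminal cells had a median difference of 0.17 over 18 genes, above 99.6% of random lists matched on expression. Within it Ly6d and Cldn4 were higher by at least 0.5, Clu differed by 0.43, Tacstd2 by 0.31 and Krt4 by 0.16, whereas Psca, also a member, differed by -0.40. Also lower were S100a10 (-1.09), the metallothionein gene Mt1 (-1.08) and Cystm1 (-0.81).

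Chemokines that attract myeloid cells were higher in castrated luminal cells. Cxcl5, a ligand of the neutrophil receptor Cxcr2, was at 0.04 in the non-castrated library and at 0.91 and 0.84 in the castrated ones. Cxcl15 was at 0.18, 0.69 and 0.75, and Lcn2, an iron-sequestering acute-phase protein gene, at 0.56, 1.14 and 1.27. Of 10 measured members of the myeloid chemoattractant list 3 were higher by at least 0.5 (Cxcl5, Cxcl15 and Cxcl2) and none lower, with a median of 0.07. Cxcl2 in luminal cells was at 0.55% of its level in neutrophils, so free RNA from neutrophils cannot be separated from it. Of the list of NF-kB and acute inflammatory genes 3 of 20 were higher by at least 0.5 (Cxcl5, Lcn2 and Cxcl2) and none lower, with a median of 0.09. MHC class I genes had a median of 0.16, with H2-K1 higher by 0.58 as the only one of 13 that reached 0.5, and H2-Q4 at 0.19, 0.77 and 0.54. The interferon response list had a median of 0.09 with none of 21 genes reaching 0.5.

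In luminal cells 86 of 1464 genes over the expression floor differed, 56 higher and 30 lower in the castrated libraries, and 70 and 50 without castrated library 2. No gene differed by 0.5 between the castrated libraries themselves. With the log taken of the mean back-transformed value plus 0.1, 339 were higher and 121 lower. Markers of RNA quality moved with the groups in this class: the mitochondrially encoded list had a median of 0.63 and the immediate early list, which responds to tissue dissociation, a median of 0.33, while nuclear oxidative phosphorylation genes had a median of -0.27 (-0.35 and -0.18 in castrated libraries 1 and 2). Genes of the seminal vesicle list were lower in castrated luminal cells as in every other class, and muscle genes (median -0.13) were near 0 in both castrated libraries. Different clusters held the class in each group, with 5 of 9 over 90% non-castrated and 4 over 90% castrated.

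Fibroblasts were compared in 1061, 58 and 56 cells. Extracellular matrix genes were lower in the castrated libraries. Of 26 measured matrix genes 13 were lower by at least 0.5 and none higher, and the list's median was -0.50, against -0.12 for all genes over the expression floor in this class. The collagen genes Col3a1 (2.92 in the non-castrated library, 1.02 and 1.12 in the castrated ones) and Col1a2 (2.71, 1.30 and 1.44), fibronectin Fn1 (1.89, 0.39 and 0.48) and Sparc (2.94, 1.60 and 1.83) had the largest differences. Of 6 complement genes 3 were lower by at least 0.5, among them C3 (3.06, 1.27 and 1.52) and C4b (1.66, 0.47 and 0.51), and the list's median was -0.58. The Upk3b-led clusters, left out of this class, had C3 at 4.09 (76 castrated cells) and 4.23 (26 non-castrated cells). The C3 difference therefore depends on that naming rule. Sult1e1, which encodes an oestrogen sulfotransferase, had the largest difference of the class at -2.33, followed by Ly6a (-2.02). The growth factor gene Igf1 was at 1.90, 0.26 and 0.32 and the haptoglobin gene Hp at 1.63, 0.04 and 0.05. Ly6c1 and Clec3b differed by -1.55 and -1.5. The androgen response list had a median of -0.26 over 8 genes, with Steap4 at -0.39 and Fkbp5 at -0.29. Its largest members, Spink1 and Sbp, also appeared in every other non-castrated class.

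Higher in castrated fibroblasts were Igfbp3, an insulin-like growth factor binding protein (0.11, 1.83 and 1.83), Mgp, a matrix protein that inhibits calcification (1.85, 3.22 and 3.38), Ifitm1 (0.72, 1.90 and 1.83) and the transcription factor gene Cebpb (1.59, 2.66 and 2.58). Interferon response genes had a median of 0.12, with 4 of 23 higher by at least 0.5, namely Iigp1 (0.91), Irf1 (0.89), the chemokine Cxcl10 (0.87) and Isg15 (0.58). The NF-kB list had a median of 0.07 with Icam1 and Nfkbia higher by 0.69 and 0.52. MHC class I genes had a median of 0.19 with none reaching 0.5. Contractile genes had a median of 0.13, with Acta2 at 0.10, 0.30 and 0.40 and none reaching 0.5. The cell cycle list had a median of 0.07 over 7 measured genes, with none reaching 0.5. The senescence list (median 0.02) went both ways, with Igfbp3 and Cdkn1a higher and Igfbp4 and Timp2 lower by at least 0.5, and lay inside the central range when cells were rescaled or members far higher in another class were left out.

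In fibroblasts 212 of 1967 genes differed, 65 higher and 147 lower. With each cell rescaled to the same total the count was 79 higher and 104 lower, and the median difference of all genes moved from -0.12 to -0.06. With the log taken of the mean back-transformed value plus 0.1, 192 were higher and 542 lower. The stress genes Ier3 (1.25), Btg2 (1.15) and Gadd45b (1.02) were among the highest, beside Ifrd1 (0.99), and the immediate early list had a median of 0.14, with 6 members higher and Klf6 lower by at least 0.5. The castrated cells came mainly from a single cluster of 100 cells, and 1 cluster of 60 non-castrated fibroblasts had matrix values as low as the castrated mean.

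**Figure D2:**
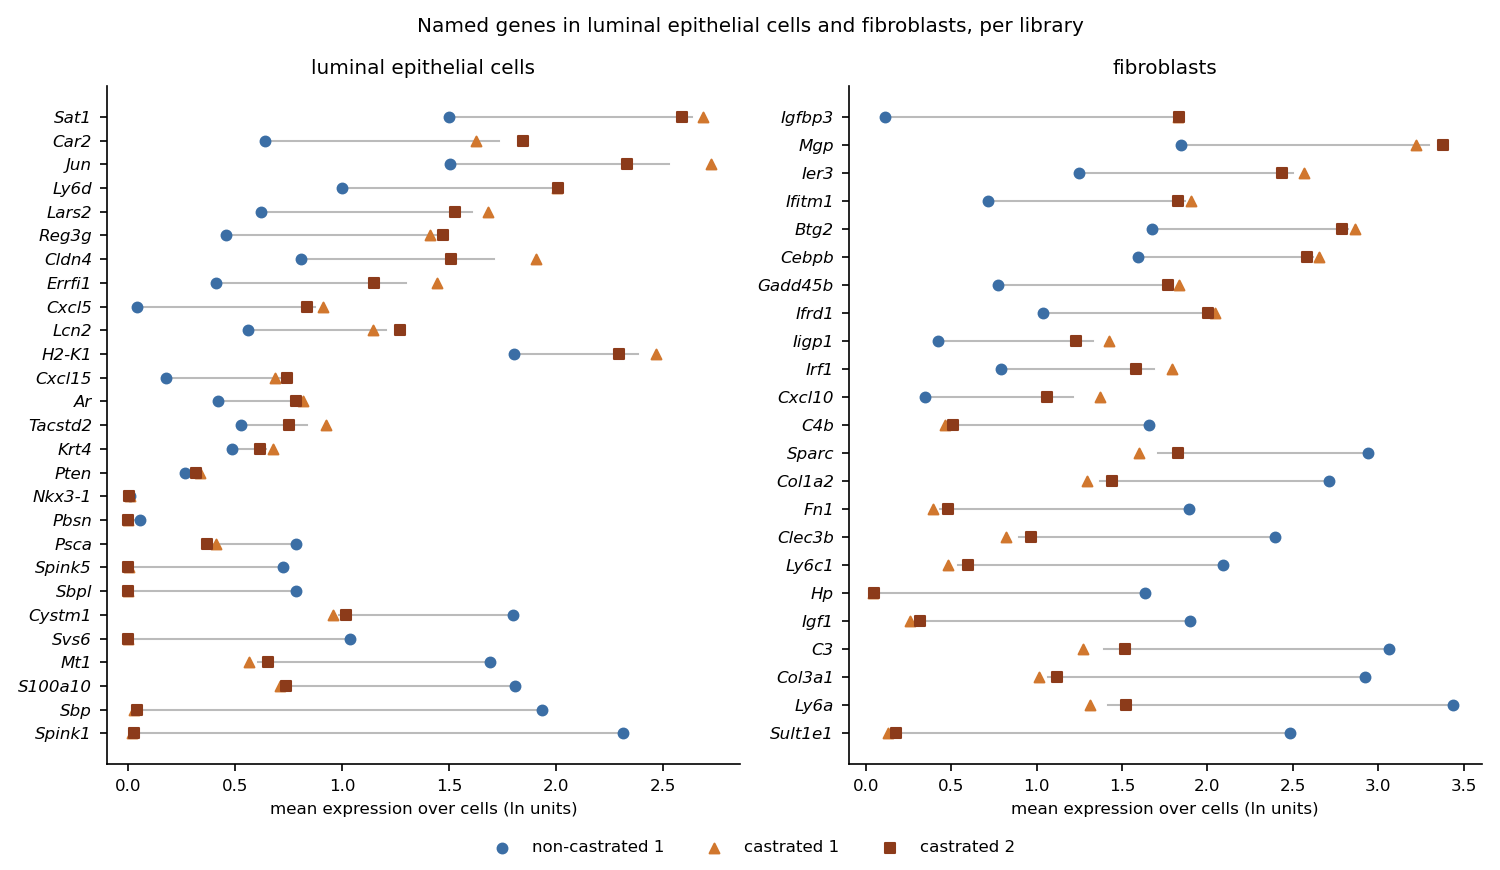
Mean expression over cells (x axis, ln units) of named genes (rows) in luminal epithelial cells and fibroblasts, with 1 point per library: non-castrated (circles), castrated 1 (triangles) and castrated 2 (squares). Grey lines join the non-castrated value to the castrated mean. Spink1 lies at 2.32 in non-castrated luminal cells and at 0.02 and 0.03 in castrated ones, and Igfbp3 lies at 0.11 in non-castrated fibroblasts and at 1.83 in both castrated libraries.

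The neutrophil comparison used 471, 1010 and 1074 cells. Slc7a11, the cystine-glutamate transporter, was the named gene most above its non-castrated level in castrated neutrophils (2.05 in the non-castrated library, 3.61 and 3.42 in the castrated ones), and Txnrd1, a thioredoxin reductase, was at 0.74, 1.59 and 1.55. Thbs1, which encodes the matrix protein thrombospondin 1, was at 1.67, 2.76 and 2.87, and Acod1, which makes itaconate, at 1.96, 3.06 and 2.77. The transporter Slc15a3 differed by 0.94, the histone demethylase Kdm6b by 0.86, Nfkb1 by 0.85 and the receptor Lilr4b by 0.80. Arg2, an arginase, was at 0.93, 1.48 and 1.43. Cxcr2 (0.15), S100a8 (0.21) and Il1b (-0.14) differed by less than 0.5.

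Interferon response genes were lower in castrated neutrophils, with a median of -0.13 over 20 genes that lay below every 1 of the 10000 random lists. Rsad2 was at 0.91, 0.53 and 0.34, Ifit1 at 0.53, 0.19 and 0.12, and none reached 0.5. Rsad2 and Ccl4 were among the leading genes of a cluster of 39 non-castrated neutrophils. At resolution 2 Rsad2 was also among those of a cluster of 54 castrated neutrophils. The differences of these genes may therefore depend on the mix of such cells in each library, which was not tested. Nuclear oxidative phosphorylation genes had a median of -0.16 with none of 23 reaching 0.5. Myeloid chemoattractants had a median of -0.08 (-0.01 in castrated library 1), with the chemokine Ccl4 lower by at least 0.5 (2.56, 2.03 and 1.69) while Cxcl2 was at 5.05, 5.58 and 5.06, so its difference came from castrated library 1. This list stayed outside the central 95% of random lists neither without castrated library 2 nor without members that are far higher in another class. MHC class I genes had a median of -0.08 (-0.05 in castrated library 1), which lay inside the central 95% of random lists when cells were rescaled, without castrated library 2, and without members that are far higher in another class. The list of castration-tolerant luminal genes (0.04) and cholesterol synthesis (0.03) lay above the central range by small amounts, the former only with castrated library 2 included. Only 1 measured member of the former reached 10% of its level in its highest class, so it could not be placed without the others. Cst3 (-0.69), the cyclophilin gene Ppia (-0.68), Lgals3 (-0.63) and Ifitm3 (-0.57) were also lower.

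In neutrophils 70 of 1237 genes differed, 41 higher and 29 lower, and 2 genes differed by 0.5 between the castrated libraries. The split was 37 higher and 19 lower without castrated library 1 and 50 and 45 without castrated library 2. With the log taken of the mean back-transformed value plus 0.1, 141 were higher and 178 lower. Spink1, Svs6 and Sbp were lower in castrated neutrophils by 1.51, 0.94 and 0.94, and these epithelial secretory transcripts were present in every class of the non-castrated library, as was Svs5, at 1.59 to 2.48 ln units outside the seminal vesicle cluster against 0.03 or less in the castrated classes.

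T cells were compared in 812, 84 and 89 cells. Genes of cytotoxic T cells were lower in the castrated libraries. Cytotoxic effector genes had a median of -0.15 over 13 genes, at -0.21 in castrated library 1 and only -0.06 in castrated library 2. Of these Ccl5 (2.60 in the non-castrated library, 1.31 and 1.65 in the castrated ones) and Nkg7 (2.27, 1.23 and 1.64) were lower by at least 0.5, while Gzmk differed by -0.34 and Gzmb was at 0.71, 0.46 and 0.65. Natural killer cells had a class of their own only in the non-castrated library. The natural killer gene Klrb1c was at 0.10, 0.15 and 0.27 in the T cell class, so the cytotoxic values may compare unlike mixtures of cells. Both chains of the CD8 co-receptor were lower, with Cd8b1 at 1.34, 0.55 and 0.67 and Cd8a at 1.20, 0.56 and 0.69. Both were among the leading genes of non-castrated clusters of 198 and 45 cells and of no castrated T cell cluster. The CD8 differences may therefore depend on the mix of T cell subsets in each library. Ms4a4b and the survival gene Bcl2 differed by -0.79 and -0.59. Inhibitory receptor genes had a median of -0.06 over 9 genes (-0.03 in castrated library 2) with none reaching 0.5, and Pdcd1, which encodes PD-1, was at 0.93, 0.69 and 0.69. MHC class I genes had a median of -0.17, interferon response genes -0.04 and MHC class II genes -0.04 (-0.07 in castrated library 2), with none reaching 0.5. The last list lost its place outside the central range without castrated library 2. None of its 6 measured members reached 10% of its level in its highest class (Cd74 was at 0.181%), so free RNA cannot be separated from it.

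Higher in castrated T cells were Rnaset2a (0.29, 1.10 and 1.10), Emb (1.36, 2.19 and 2.01), S100a4 (1.40, 2.14 and 2.06), Fosl2 (0.84, 1.53 and 1.52) and Rora, a nuclear receptor of innate-like lymphoid cells (0.72, 1.5 and 1.29). S100a4, Emb and Rora were among the leading genes of a castrated cluster of 83 cells. In the non-castrated library S100a4 and Emb led a cluster of 40 cells, and Emb was among the leading genes of another of 119. A further cluster, with 77 non-castrated cells, had S100a4 among them. The differences of these 3 genes may therefore depend on the mix of T cell subsets in each library. Rgs2 differed by 0.64, Eprs by 0.63 and Ifrd1 by 0.61. The NF-kB list had a median of 0.09 (0.13 and 0.04 in castrated libraries 1 and 2), the Pten pathway list 0.05, with Foxo1 at 0.25, and the alternative activation list 0.11, with Il4ra at 0.18; none of their members reached 0.5. The NF-kB and Pten pathway lists lay inside the central range without castrated library 1. Foxp3, the regulatory T cell factor, was at 0.14, 0.21 and 0.13, so the castrated libraries lay on both sides, and Ifng differed by -0.08. The immediate early list had a median of 0.16. In all, 31 of 1780 genes differed, 17 higher and 14 lower, and Spink1 and Sbp were again among the lower ones. With the log taken of the mean back-transformed value plus 0.1, 121 were higher and 35 lower. Only 2 of the 9 T cell clusters were mainly castrated.

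**Figure D3:**
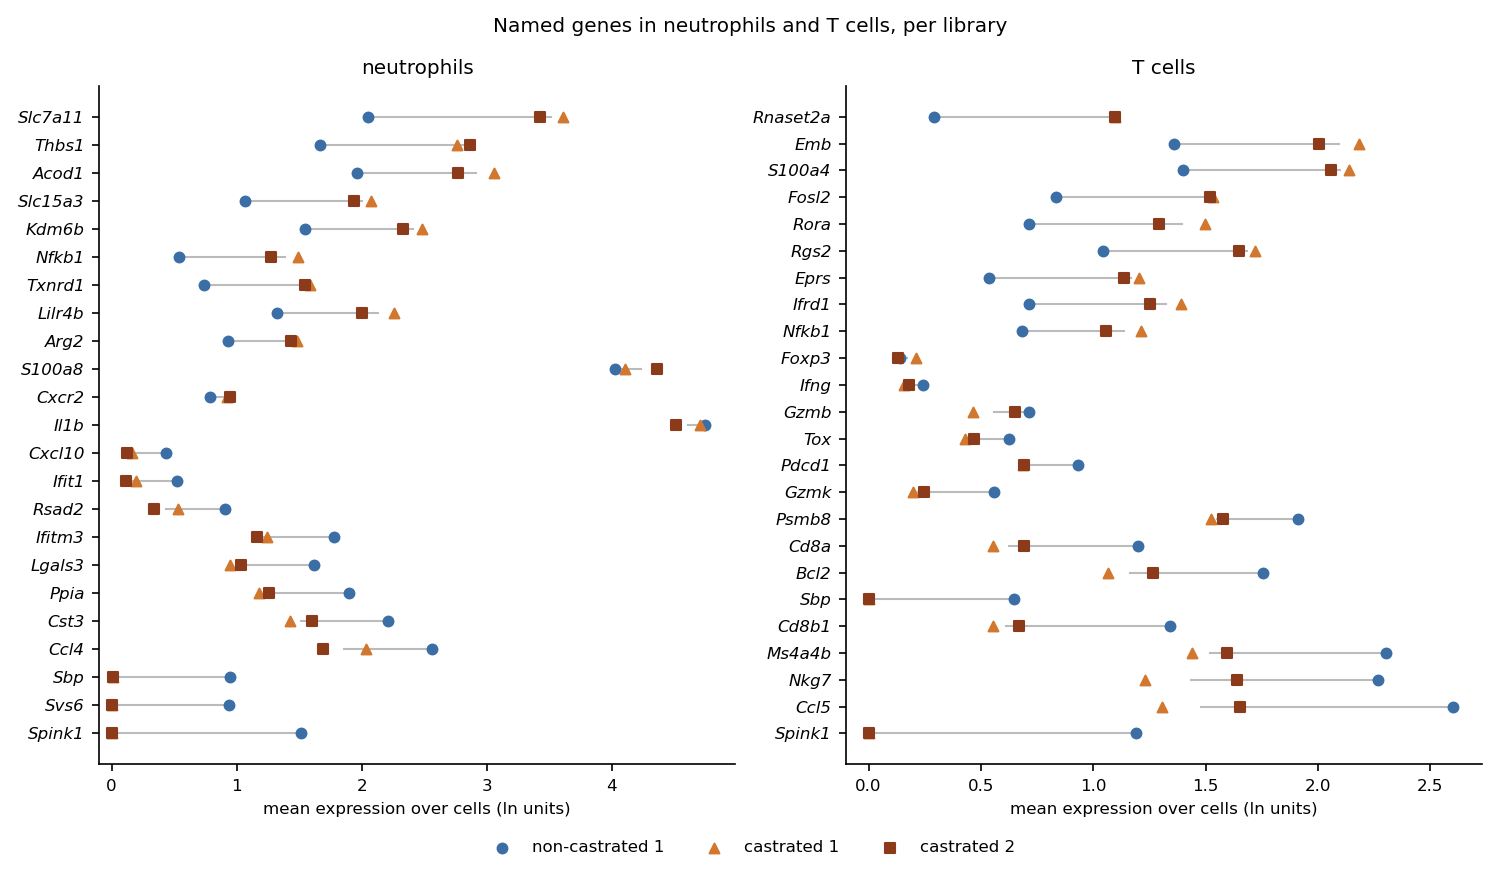
Mean expression over cells (x axis, ln units) of named genes (rows) in neutrophils and T cells, with 1 point per library: non-castrated (circles), castrated 1 (triangles) and castrated 2 (squares). Grey lines join the non-castrated value to the castrated mean. Slc7a11 in neutrophils lies at 2.05 in the non-castrated library and at 3.61 and 3.42 in the castrated ones, and Cd8b1 in T cells at 1.34, 0.55 and 0.67.

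Macrophages numbered 269, 27 and 33 cells, too few for the count of differing genes, and values alone are given. The complement gene C1qa was at 2.31 in the non-castrated library and 3.04 and 3.49 in the castrated ones, and the lipoprotein gene Apoe at 4.26, 4.40 and 4.96. The lipid receptor gene Trem2 was at 0.60, 0.49 and 0.50, Spp1 at 0.18, 0.17 and 0.13, the mannose receptor gene Mrc1 at 0.26, 0.17 and 0.12, and Arg1 at 0.04, 0.25 and 0.16. All genes over the expression floor had a median difference of -0.27 in this class. When clusters with none of their own markers among the 10 leading genes were left out, the C1qa difference turned from 0.96 to -0.64, so its direction rests on the naming of a non-castrated cluster of 134 cells.

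Over the 4 main classes, 47 of 95 list medians lay outside the central 95% of random lists matched on expression. This describes these libraries only, since members of a list move together. Of the 47, 32 stayed outside on the same side when members under 10% of their level in their highest class were left out, and 43 when cells were rescaled to the same total. In luminal cells the neutrophil maturation list (0.09) and the matrix list (-0.09) were lost in the first of these, and so was the neutrophil maturation list in fibroblasts (0.03). The neutrophil maturation list was also lost under rescaling in both classes, without castrated library 2 in luminal cells and without castrated library 1 in fibroblasts. The classical activation list in fibroblasts had a median of 0.05, with Cxcl10 higher, and castration-tolerant luminal genes in fibroblasts a median of 0.06 and a mean of -0.17, opposite in sign. The latter list could not be placed without members far higher in another class, where the 4 that remained had a median of -0.19.

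**Figure D4:**
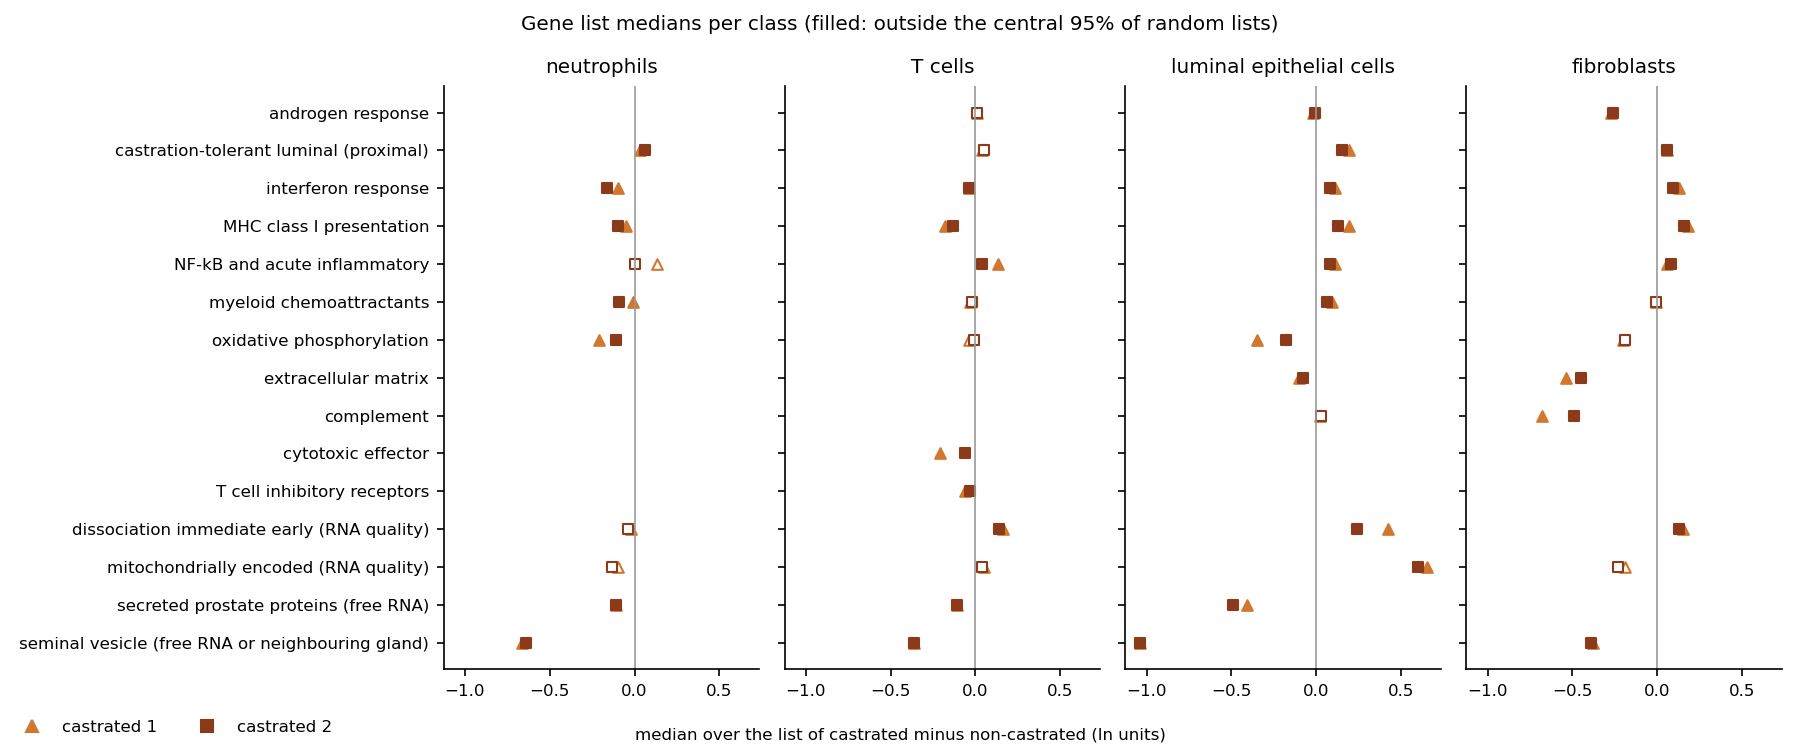
Median over each gene list (rows) of the difference from the non-castrated library (x axis, ln units), for castrated libraries 1 (triangles) and 2 (squares) in 4 cell classes. Filled points mark lists outside the central 95% of random lists. The matrix list in fibroblasts lies at -0.54 and -0.45 and the interferon list lies below 0 in neutrophils and above 0 in fibroblasts.

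In the mouse genome build mm10 (GRCm38, GENCODE vM21 annotation), 6 of the protein-coding genes named above lie as follows. Spink1 is on chromosome 18 from 43728082 to 43737557 and Slc7a11 on chromosome 3 from 49892526 to 50443614. Cxcl5 (90759360 to 90761624) and Cxcl15 (90794534 to 90803067) are neighbours on chromosome 5. Igfbp3 is on chromosome 11 from 7206086 to 7213923 and Col3a1 on chromosome 1 from 45311538 to 45349706.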

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

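The comparison with neutrophil RNA, both tests of seminal vesicle genes and the test of dilution in fibroblasts were chosen after the results they bear on had been seen.

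List medians lay on opposite sides of 0 in different classes. The MHC class I list was higher in castrated fibroblasts (median 0.19) and lower in castrated T cells (-0.17), 0.36 apart. The interferon response list was higher in fibroblasts (0.12) and lower in neutrophils (-0.13), 0.25 apart. Its member Rsad2 was among the leading genes of a cluster of 39 non-castrated neutrophils, so the neutrophil value may depend on the mix of such cells. The myeloid chemoattractant list was higher in luminal epithelial cells (0.07) and lower in neutrophils (-0.08), 0.15 apart. Its neutrophil median was only -0.01 in castrated library 1, against -0.02 for random lists, and lay inside their central 95% without castrated library 2 or without members far higher in another class. None of these differences between classes was tested.

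Cxcl5, Cxcl15 and Lcn2 were higher in luminal cells of both castrated libraries, by 0.67 ln units on average. RNA from the many neutrophils, free or brought in by smoothing, is argued against, since Cxcl5 and Cxcl15 reached at most 0.058 and 0.022 in castrated neutrophils and Lcn2 0.46, all below the luminal levels. Stress of dissociation is argued against as the whole cause, since within 5 strata of luminal cells with similar immediate early expression the mean difference was 0.71, or 106.0% of its size, and lay between 0.47 and 0.86 in each. A difference between animals or ages, or the separate smoothing, cannot be told apart from castration with 1 non-castrated library. A response of luminal cells to castration that may attract neutrophils therefore stays a hypothesis.

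Seminal vesicle transcripts appeared in every class of the non-castrated library and hardly in the named castrated ones, while Pate4 was at 4.16 in an unnamed castrated cluster of 69 cells. Free RNA from seminal vesicle cells is a candidate source, but the proportions of the 9 listed genes followed those of the seminal vesicle cluster with a correlation of only 0.74 in the least similar class, across genes that are not independent, below the 0.9 set for it and above 0.7. A list member, 9530002B09Rik, was highest in luminal cells, so the list mixes glands. Smoothing over cell types was tested by the share of their own level that luminal and fibroblast markers reach in T cells, which was 0.57 times that of seminal vesicle genes, between the bounds set, with luminal markers at 1.56% and fibroblast markers at 0.35% against 1.69%. Both explanations stay open, and so does loss of the gland's secretion after castration.

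Matrix genes were lower in castrated fibroblasts. Dilution by smoothing over other cell types, where fibroblasts are few, stays open. Of the 536 genes highest in fibroblasts, 23.3% were higher in both castrated libraries and 25 were so by at least 0.5. A higher castrated level can itself place a gene in this set, as may hold for Igfbp3 (0.11 in non-castrated fibroblasts, 1.83 in castrated ones). The share of higher genes therefore cannot decide on dilution. In the same set 103 were lower by at least 0.5 and the median was -0.2. Another mix of fibroblast states may account for the lower matrix values. Of the 7 fibroblast clusters with non-castrated cells, 1 with 60 such cells had a matrix median -0.07 from the castrated mean. The others lay 0.20 to 0.59 above. Castration stays open too.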

How the results depend on the processing

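The settings without a mitochondrial limit, without clusters lacking an own leading marker, and with rescaled cells were chosen after seeing the data. Share differences are castrated minus non-castrated in percentage points. The share differences of neutrophils, T cells and B cells moved by less than 1 SD of the castrated libraries under each setting that kept both; leaving 1 of 2 out cannot move a mean by 1 SD. The fibroblast share difference went from -36.5 to -5.9 with cells named by their highest marker mean and reversed to 5.1 without a mitochondrial limit, because the Upk3b-led castrated cluster was named fibroblast. The macrophage difference went from -11.4 to -9.1 with the highest marker mean and to -4.5 without clusters lacking an own leading marker, where C1qa in macrophages turned to -0.64. The basal difference went from 15.8 to 23.3 with a mitochondrial limit of 10%. The cause was not tested for the basal and marker mean values. With a pseudocount of 0.1 on back-transformed means, genes differing by 0.5 went from 70 to 319 in neutrophils, 31 to 156 in T cells, 86 to 460 in luminal cells and 212 to 734 in fibroblasts, since this scale compresses low values less. Total counts under the other settings stayed within 1.5 times, but lower genes went from 29 to 19 and 45 in neutrophils and from 30 to 50 in luminal cells when 1 castrated library was left out; dropping the filter on low values removed or added no counted gene and so tested nothing. Leaving out each castrated library gave 56 to 95, 25 to 33, 67 to 120 and 203 to 230 genes in these classes, 47 to 49 lists, and share differences of 56.4 to 63.9 (neutrophils), -35.1 to -34.5 (T cells), -11.7 to -11.1 (macrophages), -8.4 to -5.6 (B cells), 13.9 to 17.7 (basal cells) and -39.5 to -33.6 (fibroblasts). Of 1130 values of named genes that differed by 0.5, 1 changed sign; of 1300 values of smaller differences, 19 did. Of all 2430, 674 moved by over 1 SD, 206 of them with the other pseudocount, 111 with rescaling and 102 without a mitochondrial limit. The 2430 include 243 values for each castrated library left out, which could not move by 1 SD. Genes with both castrated libraries on the same side could not change sign there either. Count models, doublet, UMI and thinning alternatives, set tests with other correlations and the share of cycling cells were not run because the values are not counts; depth is unknown. No paired analysis was possible because the groups share only 1 replicate number and no test was made.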

Other observations

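The classes and clusters below were looked at after the data were seen, with the same rules for size and free RNA, and values are in ln units for the non-castrated library and castrated libraries 1 and 2.

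Blood endothelial cells (93, 25 and 17 cells) had higher Irf1, an interferon-induced transcription factor gene, in the castrated libraries (1.08, 2.18 and 2.25) and higher Socs3, a cytokine signalling inhibitor gene (1.92, 2.78 and 2.81). Their interferon list had a median difference of 0.13, above all 10000 random lists, with 2 of 23 genes higher by at least 0.5. Among the lowest genes were Col4a1 at 1.99, 0.87 and 0.89, Col4a2 at 1.66, 0.46 and 0.48 and Sparc at 3.21, 1.41 and 1.48, while the matrix list had a median of only -0.09 with 4 of 14 genes lower by at least 0.5. The immediate early list had a median of 0.21 in the same cells, and the lymphatic gene Ccl21a was at 0.10, 1.26 and 1.16, so castrated lymphatic cells were not separated from this class.

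Castrated macrophages had lower levels of several genes, with Il1b at 3.24, 1.57 and 1.29, Cd14 at 2.85, 1.16 and 0.98 and Nfkbia at 2.13, 0.68 and 0.46. The NF-kB list had a median of -0.35 with 8 of 23 genes lower by at least 0.5, and the immediate early list a median of -0.73 with 15 of 22, against a median of -0.27 for all genes over the floor. This is the opposite direction to the immediate early list in luminal cells (0.33) and T cells (0.16). Lysosomal Acp5 was at 0.49, 1.14 and 1.28. Krt8, a luminal keratin, was at 0.08, 0.38 and 0.42 in these macrophages. Of the 269 non-castrated macrophages, 134 came from a cluster with none of its own markers among its leading genes. Il1b and Cd14 were among those leading genes, so their differences depend on the naming of that cluster. Back-transformed sums per macrophage had medians of 7400, 4848 and 4735, and the immune gene Ptprc was at 1.75, 0.69 and 0.48.

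Castrated basal cells (36, 50 and 88 cells) had Sprr1a, a cornified envelope gene, at 0.89, 2.07 and 2.01, Errfi1 at 1.56, 2.80 and 2.67 and Sfn at 2.72, 3.64 and 3.54. Ly6a was lower, at 3.08, 1.81 and 1.90. The list of castration-tolerant luminal genes had a median of -0.36 in basal cells, with 7 of 18 lower by at least 0.5, whereas it was 0.17 in luminal cells.

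An immune cluster of 85 cells without a name was almost confined to castrated library 1 (80 cells, 6.38% of its immune cells, against 5 cells or 0.41% in castrated library 2 and 0 of 1944 non-castrated immune cells). Its leading genes included Retnlg (4.62), Thbs1 (4.22), Ccl6 (3.75), Serpinb2 (2.47) and Il1rl1 (2.26). Among epithelial cells, 59 non-castrated cells were led by Akr1b7 (6.71) and Crisp1 (4.69), and 69 castrated cells by Pate4 (4.16) and Folr1 (2.36).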
